A study of Mus musculus with 14 samples.

How the data were processed

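Single neurons of the mouse medial vestibular nucleus were collected from 3 reporter lines (YFP-16, GIN and GlyT2-13) on the C57BL/6 background at 24 to 32 days after birth. Per the labels, the authors amplified cDNA from each cell, classified the cells into types, pooled the cDNA of each type and made biotin-labelled cRNA for Affymetrix arrays. The 14 arrays analysed are 2 technical replicates of each of 7 pools. The number of cells per pool is not stated in the labels.

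The deposited values are log2 signals, which the authors made with affy and GCRMA, a method that adjusts for background, normalizes between arrays and summarises probe sets. Versions are not stated, and the log base was taken from the usual output of GCRMA and from the values, which run from a shared floor of 2.387 to 15.9. They were not centred or rescaled further. The table holds 30843 probe sets, and which others were left out before is not stated. Of these, 64 are controls, 24034 map to 1 gene symbol in the platform annotation, 477 to several and 6268 to none. Symbols were checked through Entrez identifiers against the RefSeq annotation of GRCm38.p6, where 23883 matched. Signal over background takes the place of depth here. On each array 53.998% to 56.776% of probe sets lay at the floor and 15.1% to 16.3% reached 5.

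Computation used R 4.3.3 with limma 3.58.1, and figures matplotlib 3.10.9 with pandas 2.3.3. Each of 16244 genes was represented by its 1-symbol probe set with the highest mean over all arrays, a choice that 5276 genes with several probe sets required. A gene was kept when at least 1 type had a mean of 5 or more, which left 4409 (27.1%). Of the kept genes, 123 bear clone-type names and were counted but not named.

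Because the 2 arrays of a type share a pool, the pool is the replicate. E against I was tested on 7 pool means, with 2 E and 5 I pools and 5 residual degrees of freedom. I1 against I3 was tested on the same means in a fit with 4 families (E, I1, I2 and I3) and 3 residual degrees of freedom. E1 against E2, I1a against I1b and I3a against I3b were tested on all 14 arrays with 1 mean per type, so that the error is technical. Every fit used lmFit and eBayes with an intensity trend, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1 log2 unit. Differences are the first-named group minus the second. The p-values given with differences are limma's moderated tests.

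A set of 26 gene lists was fixed before the data were examined, as were the comparisons, the thresholds and most alternatives. The lists cover transmitter identity, ion channels, fast-spiking channels, neurofilaments, fast release synaptic genes, synaptic vesicles, calcium-binding proteins, neuropeptides, transcription factors, receptors, perineuronal nets, axon guidance, oxidative phosphorylation, immediate early genes, markers of other cell types and sex-linked genes. For each list the members called were counted over all genes and adjusted over the list alone. In the E against I and I1 against I3 fits, 19 lists with at least 3 genes kept were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. With the estimated correlation no list passed in either comparison.

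Genes named per comparison were the 10 with the largest difference in each direction among called genes without overlap between groups (by size among non-overlapping genes where fewer than 10 were called), up to 4 per list with the largest absolute difference, and 6 transmitter genes. Of these, the text uses genes that differed by at least 1 log2 unit, a narrowing chosen after the data were examined, and the transmitter genes. Per type, the 6 genes with the largest gap above all other types were eligible. That count has no test, as each type has 1 pool: the lower of the 2 arrays had to lie at least 1 log2 unit above the highest array of the other types.

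List scores were means of gene-centred pool means. Their correlations over 7 pools, and the similarity of types paired by name, were tested by exact permutation. Control transcripts of the array were not used in any fit. Bacterial controls were correlated with list scores in the same way where the 3' probe set read 5 or more in at least 1 pool. Only probe sets without r2 in their name were considered for this.

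Simulated data of 4409 genes were used to test the fits, with known changes in 66 or 67 genes per size. For E against I, 79.1% of genes changed by 2 log2 units, 91.0% by 3 and 97.0% by 5 were called, with 7 false among 185 calls. For I1 against I3 the shares were 88.1%, 94.0% and 100%, with 21 false among 209. For the pair comparisons 97.0% to 98.5% of changes of 1.5 log2 units were called, with 0 to 2 false calls. Noise was drawn independently per gene at the spread each fit had already estimated, so these shares do not give the power on real genes. In the real E against I fit, 1 gene was called while 318 differed by at least 1 log2 unit.

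Alternatives were no filter, a filter at 7, the mean of a gene's probe sets, each probe set on its own, quantile normalization, centring arrays on their median, values under 5 set to 5, no intensity trend, fits of 14 arrays with the pool as a random block with and without a replicate block, leaving out each replicate or pool, Spearman correlation and a gap of 2 log2 units. Leaving out the I1b and I3a pools together, and the partner pool of each type, were added after the data were examined. The type E3 that the design names was not analysed here, and probe sets of several or no symbols were not used.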

Results

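Gene expression was measured in 7 types of neuron from the mouse medial vestibular nucleus, a brainstem nucleus that relays signals of head motion and, with the cerebellum, adjusts eye and head movements. The study classified single neurons from 3 transgenic reporter lines by transmitter genes, ion channels and cell type markers, and pooled their amplified cDNA by type. The types named E1 and E2 are classed as excitatory, and I1a, I1b, I2, I3a and I3b as inhibitory. Each pool was hybridised to 2 arrays, the technical replicates, which gave 14 arrays. Mice were of the C57BL/6 background and aged 24 to 32 days after birth. The design names a further excitatory type, E3, which was not analysed here. With 1 pool per type, the number of pools limits the precision of every statement on cell types.

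Of 16244 genes on the arrays, 4409 reached a mean of 5 on the log2 scale in at least 1 type. Arrays of the same pool correlated across these genes at r = 0.981 in I3a to 0.992 in I2, and arrays of different types at 0.847 to 0.960. Genes are not independent replicates, so these r carry no p. The standard deviation between arrays of the same pool was 0.19 log2 units in I2 to 0.29 in I3a. The lowest value on every array was 2.387, which is the floor of the scale. Differences that involve a level near it depend on where the floor lies.

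Transmitter genes were read first as a check of the labels. Slc17a6, the vesicular glutamate transporter of most brainstem excitatory neurons, stood at 11.11 in E1 and 10.98 in E2 on the log2 scale. It was at 3.11 in I2 and 3.19 in I3b, but at 10.48 in I1b, 8.60 in I1a and 6.93 in I3a. Slc32a1, the vesicular transporter of GABA and glycine, stood at 9.20 in I1b to 9.76 in I2 among the inhibitory pools, and at 6.60 in E1 and 5.41 in E2. Gad1, an enzyme of GABA synthesis, reached 10.75 in I1b to 12.38 in I2, against 7.80 in E1 and 6.80 in E2. Slc6a5, the neuronal glycine transporter, lay at 7.53 in I3b to 8.47 in I3a, against 6.31 in E1 and 3.33 in E2. Slc17a7, the vesicular glutamate transporter of cortical neurons, was at or near the floor in every pool, at 2.82 or below. The reporter lines YFP-16, GIN and GlyT2-13 carry regulatory sequences of Thy1, Gad1 and Slc6a5, and the study sorted cells by transmitter genes, so these levels are not independent evidence on the types.

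**Figure D1:**
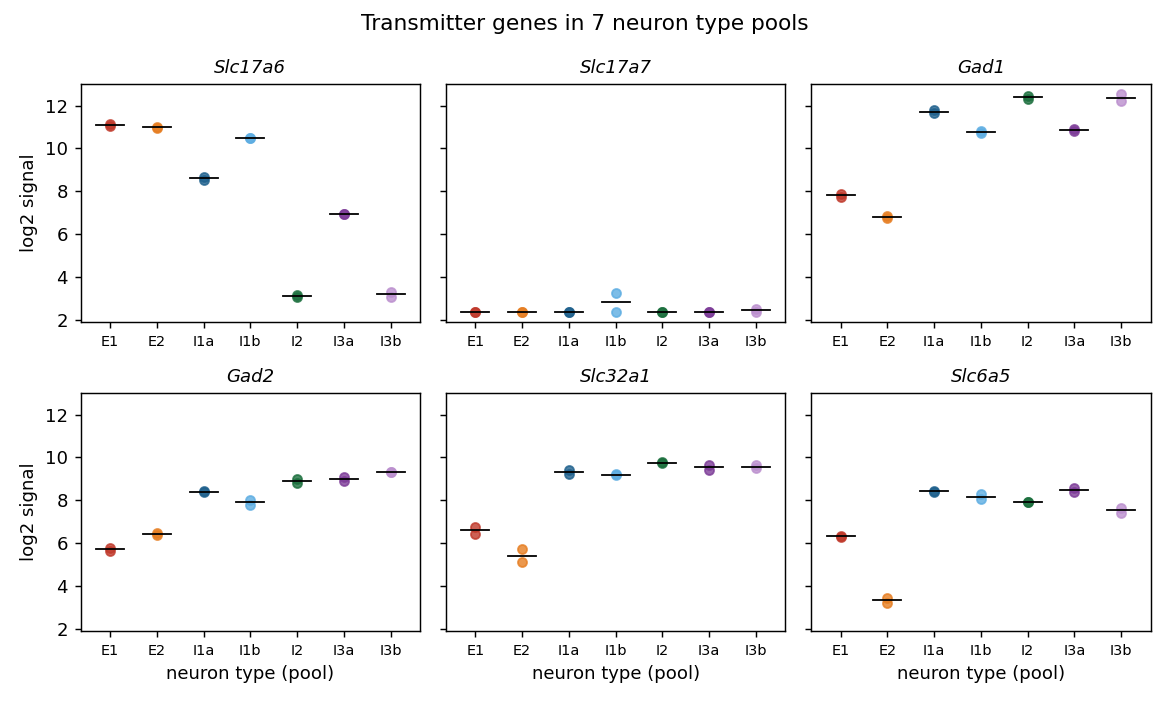
Level of 6 transmitter genes in the 7 pools on the log2 scale; points are single arrays (2 per pool) and horizontal lines are pool means. Slc17a6 reaches 10.48 in the inhibitory pool I1b, near the 10.98 of E2.

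What parts excitatory from inhibitory neurons of this nucleus was asked by comparing the 2 E pools with the 5 I pools. Slc32a1 (Entrez gene 22348, chromosome 2, positions 158607260 to 158615747 of GRCm38.p6) was the 1 gene of 4409 called. It was lower in the E pools, with a difference of -3.48 log2 units, a standard error of 0.33 and an adjusted p of 0.0396, and both E pools lay below all 5 I pools. Gad1 came next with a difference of -4.31 (SE 0.54, adjusted p 0.135), followed by Gad2, the second GABA-synthesising enzyme, with -2.64 (SE 0.40, adjusted p 0.340). Neither was called. Slc6a5 had a difference of -3.28 with an adjusted p of 0.737. Some alternatives did call them, as with a filter at 7 for Gad1 (adjusted p 0.0244). A fit of 14 arrays with the pool as a random block, which adds technical replicates to the residual, called all 3. Its adjusted p was 4.68e-05 for Gad1, 0.000686 for Gad2 and 0.00864 for Slc6a5.

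The 5 members kept of the list for GABAergic and glycinergic identity were all lower in the E pools. Of these, 1 was called over all genes and 5 adjusted over the list alone. The list stood apart from other genes by camera, with an adjusted p of 3.57e-12 at a preset correlation of 0.01, and adjusted p = 0.0556 with an estimated correlation. By fry, which asks whether the members move one way, the adjusted p was 0.00368. Because the study classified cells by these genes, the list is not independent evidence of its direction.

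Genes with higher values in the E pools were not called, and their values follow. Crh, the stress peptide corticotropin-releasing hormone, differed by 5.49 (SE 1.84, adjusted p 0.737). It stood at 13.22 in E2 and 10.87 in E1, but also at 9.69 in I3a and 8.29 in I1b, against 2.86 in I1a. Zic1, a zinc finger transcription factor of the dorsal hindbrain, differed by 3.97 and Nrn1, a secreted protein of neurite growth, by 3.95. Thy1, a surface protein of projection neurons, differed by 3.26, and Pcp4, a calmodulin regulator, by 3.17. The reporter line YFP-16 carries regulatory sequences of Thy1, so the Thy1 level is not independent evidence on the types. Values lower in the E pools, also uncalled, included Stx1a, a plasma membrane fusion protein of nerve terminals, at -3.08, Synpr, a synaptic vesicle protein, at -2.86, and Calb2, the calcium-binding protein calretinin, at -2.36. Calb2 varied as much among the I pools, from 3.44 in I3a to 10.20 in I2.

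Ion channels of fast-spiking neurons had positive differences in all 6 members kept, with a median of 1.38. None was called over all genes, and 1 was higher adjusted over the list alone. Scn4b, a sodium channel subunit that speeds repetitive firing, differed by 4.47 (SE 1.88), Kcna1, an axonal potassium channel, by 2.49 and Scn8a, the main sodium channel of nodes and axon initial segments, by 1.52. The 4 neurofilament genes kept were also all positive, with Nefh at 2.66 and Nefm at 2.38, and none called over all genes or adjusted over the list alone. Camera gave an adjusted p of 0.000353 for the channels, but adjusted p = 0.657 with an estimated correlation. For the neurofilaments it gave 0.00272, and adjusted p = 0.657 with an estimated correlation. Channels were among the genes by which cells were classified, so that list is not independent evidence. Beside both lists, the signal of a bacterial control transcript, Lys, read 10.37 in E2 and 10.49 in E1 against 10.65 in I1a to 12.003 in I3a, while another, BioB, read 8.98 in E2 and 8.23 in E1 against 7.74 in I2 to 9.62 in I3a.

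None of the other 16 lists tested passed camera, with adjusted p from 0.313 to 0.983. Stx1a, lower adjusted over the list alone, was the 1 such gene among the 5 fast release genes kept. In all, 273 genes had an unadjusted p under 0.05 and 318 differed by at least 1 log2 unit. Over all 4409 genes the means of the E pools and I pools did not overlap for 537 (12.2%), where pools without order would part for 9.52%. The Slc32a1 call ended without replicate 1 of each pool (adjusted p 0.0542), without the intensity trend (0.0563), and without the E2 (0.199), I1a (0.204), I1b (0.0781), I2 (0.127), I3a (0.215) or I3b pool (0.223), within a range of 6.98e-05 to 0.223 over the alternatives. Its difference in the settings that ended the call was -2.88 to -3.67, against -3.48. Single pools also decided other calls: without E1, Slc6a5 was called at -4.77 (adjusted p 0.0307), and without I1b, Cntnap5a at 3.53. With I1b and I3a left out together, a setting chosen after the data were examined, the 2 genes called were Fhod3, a formin, and Cntnap5a, both higher in the E pools, and Slc32a1 was not (adjusted p 0.164).

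How the I1 and I3 inhibitory families differ was asked with 2 pools of each. The 2 I1 pools had higher values of Scn4b than the 2 I3 pools, by 5.08 log2 units (SE 0.84, adjusted p 0.162), and of Kcna1, by 3.43 (SE 0.46, adjusted p 0.142). The same held for C1ql3, a secreted protein that binds synaptic adhesion receptors, by 4.73, for Rgs4, an inhibitor of G protein signalling, by 4.13, and for Ret, the receptor of glial cell-derived neurotrophic factors, by 3.66. The I3 pools had the higher values of Tacr3, the neurokinin B receptor, with a difference of -4.34, of Crhbp, which binds and neutralises corticotropin-releasing hormone, with -4.16, and of Gng4, a G protein subunit, with -3.98. None of these, and no gene of 4409, was called by limma on pool means, where 496 had an unadjusted p under 0.05 and the smallest adjusted p was 0.142.

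All 6 fast-spiking channel genes kept had higher values in I1, with a median difference of 1.09, and 3 were higher adjusted over the list alone. All 4 neurofilament genes did too, with a median of 1.31 and 2 higher adjusted over the list alone, among them Nefh at 3.14. Of 5 fast release genes, 2 were higher and 1 lower adjusted over the list alone. These were Syt2, a fast calcium sensor of release, at 3.23, Vamp1, a vesicle fusion protein, at 2.0, and Stx1a at -2.40. Of 17 voltage-gated potassium channel genes, 12 were positive, the median was 0.25 and 1 was higher adjusted over the list alone. Kcnc2, a channel of fast repolarisation, differed by 3.07. For the channels camera gave an adjusted p of 4.15e-07, and adjusted p = 0.522 with an estimated correlation. For the neurofilaments the values were 0.00260, and adjusted p = 0.579 with an estimated correlation. For fast release genes they were 0.0110, and adjusted p = 0.494 with an estimated correlation. For potassium channels they were 0.0174, and adjusted p = 0.494 with an estimated correlation. Channel genes helped to classify the cells, so both channel lists are not independent evidence. By fry no list of 19 passed, the lowest adjusted p being 0.12. Beside these groups, the bacterial control transcripts Lys and Dap read 10.65 and 4.57 in I1a, 10.84 and 5.09 in I1b, 12.003 and 6.14 in I3a, and 11.64 and 5.86 in I3b. BioB read 8.89 in I1a, 7.88 in I1b, 9.62 in I3a and 8.78 in I3b.

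Other I3 genes pointed to no fixed list as a whole, since the other 15 lists tested had adjusted camera p from 0.293 to 0.887. Ebf3, a transcription factor of neuronal identity, differed by -2.68 and Hoxb3, a hindbrain position gene, by -2.27. Ldha, which makes lactate from pyruvate, differed by -3.28, and Scn2a, a sodium channel of unmyelinated axons, by -2.25. Slc17a6 was higher in I1 by 4.48 (adjusted p 0.333). Gad1 differed by -0.38, with a sign that turned without I1b (0.10) or I3b (0.37). Differences of at least 1 log2 unit were seen in 442 genes. Over all 4409 genes the means of the groups did not overlap for 1762 (39.96%), where pools without order would part for 33.3%. A fit of all 14 arrays with the pool as a random block called 114 genes, 49 of them higher in I1. Other settings gave 1 gene without the low-signal filter, 1 without the intensity trend and 2 with values under 5 set to 5.

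A fast-spiking axis across all pools was examined with 3 list scores, each the mean of gene-centred log2 values. Channel scores fell into a high set, E1 at 1.52, I1b at 1.14, E2 at 1.06 and I1a at 0.36, and a low set, I3a at -1.03, I3b at -1.52 and I2 at -1.53. Neurofilament scores followed them over the 7 pools with r = 0.979 (exact permutation p 0.00159, adjusted 0.00446) and rho = 0.964 (exact p 0.00278, adjusted 0.00833). Fast release scores followed the channels with r = 0.910 (exact p 0.00298, adjusted 0.00446) and rho = 0.893 (exact p 0.0123, adjusted 0.0185). They followed the neurofilaments with r = 0.861 (exact p 0.0117, adjusted 0.0117) and rho = 0.857 (exact p 0.0238, adjusted 0.0238). Tests were two-sided over all pairings of the 7 pools, for 3 relations. Without the 2 pools farthest from the median, r was 0.990, 0.893 and 0.933 in turn. The relation was not tested within these small sets of 4 and 3 pools, so no test told it from a difference between the sets. In the high set neurofilament scores kept the channel order, at 1.62 in E1, 1.01 in I1b, 0.84 in E2 and 0.02 in I1a. Fast release scores did not, with I1b at 0.69 above E1 at 0.41. Nor did neurofilament scores in the low set, with I3b at -0.99 above I3a at -1.15. Stx1a ran against the axis, at 2.85 in E1 and 7.95 in I3b.

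Of bacterial controls read by 3' probe sets without r2 in their name, 6 reached 5 in at least 1 pool. They were set against the 3 list scores, for 18 relations, and none passed adjusted over them. Phe was left out by this choice and not correlated with the scores. Its r2 probe set read 5.65 in E1, 5.70 in E2, 5.83 in I1a and 6.19 in I1b. In I2 it read 6.65, in I3a 6.08 and in I3b 6.90. Lys ran against the channel scores with r = -0.892 (exact p 0.0246, adjusted 0.118) and rho = -0.679 (exact p 0.110, adjusted 0.493). Dap gave r = -0.895 (exact p 0.0276, adjusted 0.118) and rho = -0.714 (exact p 0.0881, adjusted 0.493). BioB, BioC, BioDn and Cre gave r = -0.166, -0.163, -0.139 and -0.203 (exact p 0.730, 0.731, 0.775 and 0.659, adjusted 0.794 for each), with rho = 0.036, 0, 0.036 and -0.179. BioB and BioC differed across pools by 1.88 and 1.74 log2 units, beside 1.64 for Lys and 1.76 for Dap, and were lowest in I2 and highest in I3a. Without the 2 pools farthest from the median of each control, r against the channel scores was -0.894 for Lys, -0.818 for Dap, -0.573 for BioB, -0.502 for BioC, -0.607 for BioDn and -0.669 for Cre. Over the 3 list scores, exact p of r ran from 0.0143 to 0.0663 for Lys and Dap. For BioB, BioC, BioDn and Cre it ran from 0.537 to 0.794. All 6 controls shared 1 adjustment, so its outcome depends on which controls are counted together. Whether and at what step these transcripts were added is not stated in the labels.

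**Figure D2:**
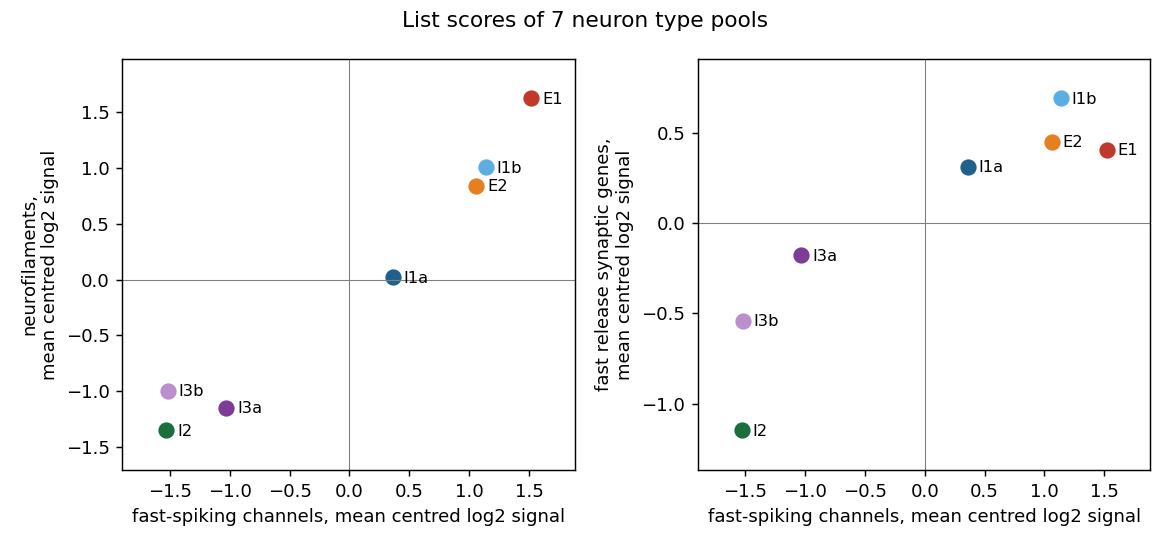
Scores of 3 gene lists in the 7 pools, each the mean over list genes of log2 values centred on the mean of the 7 pools; points are pools, named beside them. Channel and neurofilament scores run together (r = 0.979), with E1, E2 and I1b at the high end and I2, I3a and I3b at the low end. I1a lies between them, at 0.36 for channels and 0.02 for neurofilaments.

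The excitatory types E1 and E2 were compared on their 4 arrays. The p-values of this and the next pair comparisons cover technical error only, so they compare pools and not cell types. Counts of list members called were not tested against the share called over all genes, which is given for each pair. Of 4409 genes, 326 (7.39%) were called, 185 higher in E1 and 141 higher in E2. That split became 162 and 163 after quantile normalization, 161 and 164 with arrays centred on their median, and 144 and 169 without E1 replicate 1. E1 had more Htr1d, a serotonin receptor, by 3.66 (SE 0.22, adjusted p 5.39e-07), more Slc6a5, by 2.98 (SE 0.13, adjusted p 5.95e-08), and more Tafa2, a secreted neurotrophic-like protein, by 3.51. Gadd45gip1, a mitochondrial ribosome protein, was higher by 3.75. E2 had more Lpl, lipoprotein lipase, with a difference of -4.88 (SE 0.17, adjusted p 1.50e-08), more Necab1, a neuronal calcium-binding protein, with -3.68, and more Synpr, with -3.55. Crh, high in both, was higher in E2, with -2.35, as was Cxcl12, a chemokine, with -2.74.

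Of 18 hindbrain and neuronal identity transcription factors kept, 8 were higher in E2 and none in E1, and so in counts adjusted over the list alone, which were equal to those over all genes in every list named for this pair. Examples were Prdm8, a neuronal repressor, at -2.40, Neurod6 at -2.15 and Neurod1 at -1.31, which are basic helix-loop-helix factors of neuronal differentiation. Of 5 genes for GABAergic and glycinergic identity, 3 were higher in E1 (Slc6a5, Slc32a1 by 1.19 and Gad1 by 1.0) and none in E2, with 2 called after either rescaling, quantile normalization or centring of arrays on their median. Gad2 differed by -0.71 and was not called, as its size was below 1. The study classified cells by these genes, so they are not independent evidence. Of 24 synaptic vesicle and exocytosis genes, 4 were higher in E2 and 1 in E1, with Cplx2, a regulator of fusion, at -2.42 and Syt1, the main calcium sensor of release, at -2.09. Calcium-binding proteins went both ways, with Calb2 higher in E1 by 2.56 and Pvalb, parvalbumin, by 1.16. Axon guidance and adhesion genes did so too, 4 in E1 and 5 in E2 among 31, with Cdh10 at 2.72 and Sema3a at -2.27. Slc17a6 differed by 0.13. In the voltage-gated potassium channel list, of a kind also used in the classification and so not independent evidence, 3 of 17 were higher in E1 and 1 in E2, with Kcnq3 at 1.66. Beside these, the astrocyte marker S100b was higher in E1 by 1.96 (adjusted p 0.000137), as was Hspa1b, a heat shock protein of the stress list, by 1.87. The Kcnq3 value turned to -0.21 with the mean of its probe sets. The count of called genes was 193 with a filter at 7, 187 with the mean of a gene's probe sets and 217 with values under 5 set to 5.

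I1a and I1b, of the same inhibitory family by name, differed by 579 called genes (13.1% of 4409), 148 higher in I1a and 431 higher in I1b. I1b had much more Crh, with a difference of -5.43 (SE 0.14, adjusted p 6.02e-10), Zic1, with -4.29, Lpl, with -4.29, and Cntnap5a, a neuronal adhesion protein, with -3.59. I1a had more Col24a1, a fibrillar collagen, by 4.71 (SE 0.21, adjusted p 3.92e-08), Lamb1, a laminin chain, by 4.71, Igf1, insulin-like growth factor, by 3.68, and Tacr3 by 3.23. Slc17a6 was higher in I1b, with -1.88, while Gad1 differed by 0.96, Gad2 by 0.49 and Slc6a5 by 0.25, all uncalled. The median of all genes was shifted, at -0.22, and the split of called genes became 222 and 276 after quantile normalization and 227 and 256 with arrays centred on their median.

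Of 6 fast-spiking channel genes, 1 was higher in I1b, Scn4b with -2.30, and none in I1a. Of 5 fast release genes, 1 was higher in I1b, Syt2 with -1.84, and 1 in I1a, Stx1a with 1.5. Of 4 neurofilament genes, 3 were higher in I1b by the deposited values and 1 after either rescaling, with all 4 differences negative in each and Nefh at -1.45. Of 11 sodium channel genes, 4 were higher in I1b and none in I1a, with 3 when arrays were centred, among them Fgf13, a channel-associated factor, at -1.70, and Scn2a at -1.44. Of 17 voltage-gated potassium channel genes, 4 were higher in I1b, such as Kcnc2 with -3.55, and 1 in I1a, Kcna4 by 1.56. The classification of cells used channel genes, so the channel lists are not independent evidence. Of 9 GABA-A and glycine receptor genes, 3 were higher in I1b and none in I1a, with 2 after either rescaling. Gabrb2, a GABA-A receptor subunit, differed by -2.92 and Gphn, the scaffold of inhibitory synapses, by -1.67. Of 6 glutamate receptor genes 3 were higher in I1b, Gria4 by -1.29 among them, and 1 after either rescaling. Of 31 axon guidance and adhesion genes, 10 were higher in I1b and 3 in I1a, and 8 and 4 after quantile normalization. Transcription factors went both ways, with 6 of 18 higher in I1a, such as St18 by 2.86 and Neurod6 by 2.52, and 4 higher in I1b, such as Pbx3, a homeobox cofactor, by -2.11. Beside these, the oligodendrocyte markers Mbp and Cnp, proteins of myelin, were higher in I1b, by -3.07 and -1.69. So was the astrocyte marker S100b, by -1.26, though not called after quantile normalization, while the microglia marker Laptm5 was higher in I1a, by 1.05. Counts adjusted over the list alone were the same in each of these lists. The number of called genes was 304 with a filter at 7, 309 with the mean of a gene's probe sets and 358 with values under 5 set to 5.

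Between I3a and I3b, 437 genes (9.91% of 4409) were called, 132 higher in I3a and 305 higher in I3b. That split became 167 and 237 after quantile normalization and 153 and 255 with arrays centred. I3b had much more Calb2, with a difference of -6.42 (SE 0.17, adjusted p 1.44e-10), and more Cd24a, a surface glycoprotein of young neurons, with -6.41 (SE 0.08, adjusted p 1.62e-13). It had more Kitl, the ligand of the Kit receptor, with -4.58, Gpr101, an orphan receptor, with -3.98, and Penk, the precursor of enkephalin, with -3.51. I3a had more Crh, by 5.50 (SE 0.14, adjusted p 1.44e-10), Zic1, by 5.22, Pcp4, by 4.28, and Cbln4, a secreted synaptic organiser, by 4.02. Slc17a6 was higher in I3a by 3.74, and Gad1 higher in I3b, with -1.50.

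Of 4 perineuronal net and matrix genes kept, 3 were higher in I3a and none in I3b, with Bcan, brevican, at 2.56, Vcan, versican, at 2.5 and Tnr, tenascin-R, at 2.16. In the same pool the myelin genes Cnp and Mbp were higher, by 4.0 and 2.78, and they are the 2 oligodendrocyte markers kept. Of 6 monoamine, acetylcholine and opioid receptor genes, 3 were higher in I3a and none in I3b. They were Htr1d by 2.62, Htr2c, a second serotonin receptor, by 1.34 and Chrna7, a nicotinic receptor, by 1.21. Of 9 GABA-A and glycine receptor genes 3 were higher in I3a, Gabra2 by 2.75 among them. Immediate early genes were higher in I3b for 2 of 4, Fos at -2.24 and Dusp1 at -2.13, both induced by activity. Neuropeptides and secreted proteins went both ways, 3 in I3a and 4 in I3b among 14, with Igf1 at -3.08. Of 18 transcription factors 3 were higher in I3b and 1 in I3a, St18 at -3.71 and Pbx3 at 3.70. Of 24 synaptic vesicle genes 4 were higher in I3a and 2 in I3b, Syt1 at -2.77 among the latter. Of 31 axon guidance and adhesion genes 5 were higher in I3a and 3 in I3b, with Unc5d, a netrin receptor, at 2.34 and Ntng1, netrin-G1, at -3.63. Counts adjusted over the list alone were the same in each of these lists. The number of called genes was 218 with a filter at 7, 246 with the mean of a gene's probe sets and 256 with values under 5 set to 5.

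Genes with all arrays of 1 type at least 1 log2 unit above every array of the other types were most numerous in I2, with 132 of 4409 (2.99%). With a filter at 7 that count was 75, and with 1 array per type, which loosens the rule by construction, 196 to 204. The largest gaps in I2 were of Pappa, a protease that frees insulin-like growth factors, at a level of 8.23 and a gap of 4.86, Rgs5, a regulator of G protein signalling, at 7.35, and Slc6a2, the noradrenaline transporter, at 8.18 with a gap of 4.42. Rgs5, otherwise a marker of pericytes, was within 0.1 of the floor in 5 of the other pools. I3b had 15 such genes, led by St18 at 8.54, Penk at 6.16 and Igfbp5, an insulin-like growth factor binding protein, at 6.63. E2 had 12, led by Anxa4, an annexin, at 5.63, Cxcl12 at 6.99 and Crh at 13.22. I3a had 8, led by Cnp at 9.14 and Plagl1, an imprinted zinc finger gene, at 10.18. E1 had 7, led by Gadd45gip1 at 7.07 and with S100b, otherwise an astrocyte marker, at 9.02. I1a had 6, led by Efemp1, a matrix protein, at 6.60, and I1b had 3, led by Tiam2, an activator of Rac, at 8.79. I2 has no partner type in the set, while leaving out the partner of each other type raised I3a to 36 and I3b to 41 and changed the remaining counts to 8 in E1, 17 in E2, 7 in I1a and 4 in I1b. With the I1b and I3a pools left out together, a setting chosen after the data were examined, the counts were 17 in E1, 25 in E2 and 44 in I3b, and 174 in I2. The filter at 7 gave 3 in E1, 7 in E2, 2 in I1a, 1 in I1b and 3 in I3a, and 1 array per type gave 15 to 19 in E1, 22 to 23 in E2, 12 to 14 in I1a, 7 to 13 in I1b, 22 to 23 in I3a and 28 to 35 in I3b. I2 had the most genes under each of these settings.

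**Figure D3:**
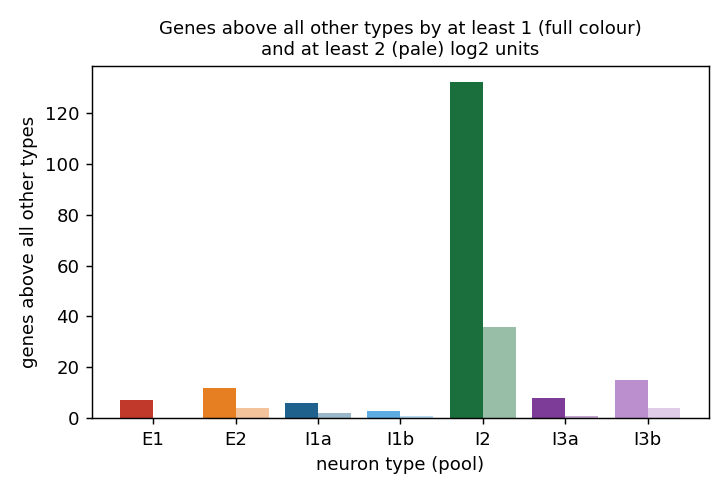
Number of genes per type whose lower array lies at least 1 log2 unit above the highest array of the other 6 types, with the number at a gap of 2 log2 units beside it; bars are counts among 4409 genes. I2 has 132, and no other type has over 15.

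Whether types paired by name resemble each other was asked with correlations of gene-centred pool means. The study sorted cells into types by transmitter genes, channels and markers, so resemblance within named pairs is not independent of the names. E1 and E2 correlated at r = 0.348 and I3a and I3b at 0.279, while I1a and I1b were at -0.149. Centring on 7 pools alone gives unrelated pools of equal spread an r of -0.167, near the value of I1a and I1b. The pool nearest to I1b was E1, at 0.357, and E2 stood at 0.206. The mean over the 3 named pairs was 0.159. Of all ways to draw 3 separate pairs from the 7 pools, 3 gave a mean as large, the named pairs included (exact one-sided permutation p 0.0286), the highest being 0.184 with E1 and I1b, E2 and I1a, and I3a and I3b. The lowest of these r was that of E1 and I3b, at -0.543, but by uncentred levels it was that of E1 and I2 (0.853, against 0.894), and I1a and I2 had the most genes differing by 1 log2 unit or more (1160, against 783).

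**Figure D4:**
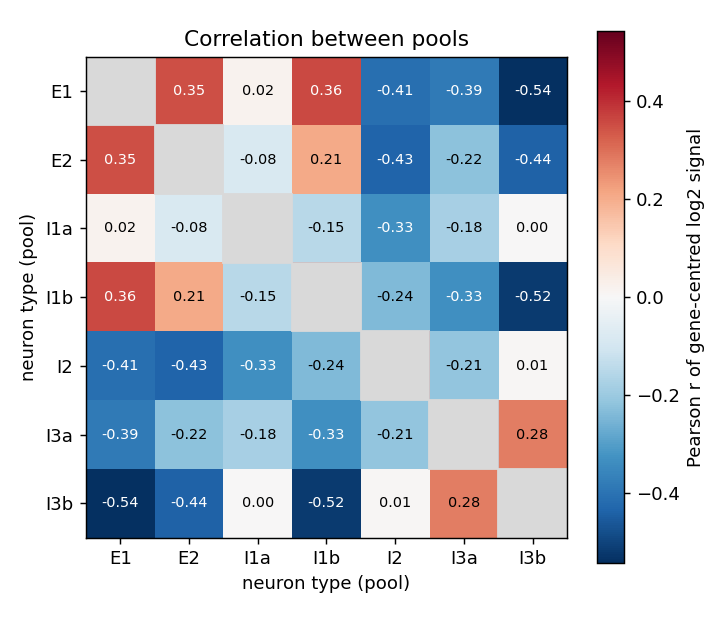
Pearson correlation across 4409 genes between each 2 of the 7 pools, after each gene was centred on its mean over pools; colour and printed number give r. I1b lies nearer to E1 (0.357) than to I1a (-0.149).

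Most markers of other cells were not kept, but those kept were not all low. Of 12 astrocyte markers 2 were kept, S100b, at 5.24 in I2 to 9.02 in E1, and Aldoc, at 11.63 in I3b to 12.32 in I1b. Of 11 oligodendrocyte markers measured, Mbp and Cnp were kept, of 9 microglia markers Laptm5, at 5.76 in I3b to 7.18 in I1a, and of 8 vascular and blood markers Rgs5, at 7.35 in I2. None of 7 cerebellar, ependymal and choroid markers was kept. Mbp stood at 6.20 in I3a and 5.50 in I1b, and Cnp at 9.14 and 6.62. Oxidative phosphorylation genes, with 64 kept, had a median difference of 0.04 between E and I pools and 0.00 between I1 and I3. Of 5 calcium channel genes kept, 1 was called between I1a and I1b, Cacna2d3, an auxiliary subunit, with -1.91, and 1 between I3a and I3b, Cacna1e, a pore subunit, with 1.12. In the list of other potassium and HCN channels, Kcnj3, a channel gated by G proteins, was higher in E1 than E2 by 1.38 and lower in I3a than I3b by -1.58. Of 2 sex-linked genes kept, both Y-linked, none was called between E1 and E2, and Kdm5d at 1.25 and Eif2s3y at -1.09 were called in opposite directions between I3a and I3b, the latter not after quantile normalization or centring.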

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

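The tests in this part were set before the values they measure were seen, and the patterns they address were chosen after the results of the comparisons were seen. For random list pairs an outcome was set for channels with neurofilaments alone, and the rule set for Lys was not applied.

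Single I pools stood far from the other 4 in 9 of 91 named genes. Chance gives about 1 in 20 groups, a rate for genes not chosen by their values, so it does not apply to these genes, named for large differences, and the count is not evidence. The value for each is the gap to the nearest pool as a share of the range over the 5 I pools. I1b stood apart for Cntnap5a (0.9335), Prkg2, a cGMP-dependent kinase (0.7678), Ndufa4, a respiratory chain subunit (0.7342), and Cntn3, an axonal adhesion protein (0.718). I2 stood apart for Rgs5 (0.9976), Gria3, an AMPA receptor subunit (0.8657), Ptprz1, a receptor phosphatase (0.863), and Kcnt2, a sodium-activated potassium channel (0.7964). I3a stood apart for Cacna1e (0.9415).

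Signals outside the genes were seen in bacterial control transcripts. Read by 3' probe sets without r2 in their name, 6 reached 5 in at least 1 pool. They differed across pools by 1.637 log2 units for Lys, 1.759 for Dap, 1.883 for BioB, 1.737 for BioC, 1.322 for BioDn and 0.7364 for Cre. BioB, BioC, BioDn and Cre were all lowest in I2 and highest in I3a, an order other than that of Lys and Dap. Phe, not among the 6, ran from 5.65 in E1 to 6.90 in I3b by its r2 probe set.

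The count of 1 gene called between E and I pools was compared with other splits of the 7 pools into 2 and 5. Of 21 splits, 3 called at least 1 gene, so chance cannot be excluded. The highest of the others was 3 genes, with I2 and I3b set against the rest, and I2 with I3a gave 1.

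The first pattern weighed is I1b, an inhibitory pool nearest in expression to E1. One candidate explanation is cDNA of E1 or E2 cells mixed into the I1b pool, which would carry every abundant E transcript along at about the share that Slc17a6 shows, 70.6% of the lower E pool. Over 1081 genes at 8 or more in both E pools, the 5th largest deficit in I1b exceeded that of Slc17a6 by 0.475 log2 units, within the 1 log2 unit set beforehand. These genes were not chosen for absence from inhibitory neurons, so a 5th deficit this small could arise with or without mixing and cannot decide. Against so large a share, Tacr3, Psg21 and Crh bounded it at 12%, 15.39% and 16.8%, if levels scale with share, though 3 genes were too few to decide by the rule set. An inhibitory type that expresses Slc17a6 remains open, since no test separated the explanations with 1 pool.

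The second pattern is the fast-spiking axis, high in E1, E2 and I1b and low in I2, I3a and I3b. An axis that any genes of like level share was argued against, as 0 of 10000 random list pairs, a share under 1 in 10000 and the smallest these draws can show, correlated as strongly as channels with neurofilaments (median r 0.191). For channels with fast release genes 1.04% of random pairs did, and for neurofilaments with fast release genes 2.34%, both less rare and under the 5% set for the first relation. Random genes were matched for level only, not for spread between pools or correlation within a list. An axis shared by highly variable genes was thus not tested. Less starting RNA in the pools with more bacterial control signal stays open. Of 10000 matched random lists 0 followed Lys as steeply, which by the rule set beforehand would argue against it. That rule was set aside, because normalization between arrays removes a general loss, so such lists centre near a slope of 0 (median 0.0227) whatever the input. The classification of cells by ion channels, and a difference in firing between types, stay open and untested.

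The third pattern is markers of other cell types in single pools. Oligodendrocyte RNA in the I3a pool is a candidate source of Cnp (9.14) and Mbp (6.20), but 0 of 9 other oligodendrocyte markers reached 5 there, Sox10 at 4.57 being the highest, as it was at 4.57 to 4.86 in every pool. Pericyte RNA in the I2 pool is a candidate source of Rgs5 (7.35) and Abcc9 (5.84), a potassium channel regulator, but 0 of 12 other pericyte genes stood 1 log2 unit above the other pools in I2, Art3 coming nearest at 4.07. No pool gave signal for most of these other probe sets, Sox10 apart, so that their power to detect such cells was not shown here, and the pericyte list shares Rgs5 and Vtn with the fixed vascular list. Expression of these genes by the neurons themselves was not tested.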

How the results depend on the processing

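Leaving out the I1b and I3a pools together or the partner pool, and reading only genes that differed by at least 1 log2 unit, were chosen after the data were examined, and the other settings before. The signal over background limits every value, since 53.998% or more of the probe sets lay at the floor. Except where a construction is named, the cause of a change was not tested.

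E against I called 2 genes without a filter, with a filter at 7 and with values under 5 set to 5, 0 without the intensity trend, 6 with 14 arrays and the pool as a random block and 5 when a replicate block was added, 0 to 2 when 1 replicate or pool was left out, and 2 without I1b and I3a (Fhod3 by 4.2 and Cntnap5a by 3.49, the latter also called without I1b alone). I1 against I3 called 1 gene without a filter, 2 with values under 5 set to 5, 1 without the trend, 114 with the random block and 104 with the replicate block, and 0 when any replicate or pool was left out, with 391 to 561 at an unadjusted p under 0.05. The arrays treated as blocks add technical replicates to the residual, which the fit of means does not. Deviations of same-numbered arrays from their pool means had a median correlation of -0.000342 over 21 pairs of types. They ran from -0.117 to 0.212, with 4 over 0.1, so a deviation shared by some arrays was not excluded. The replicate block gave 327, 579 and 436 genes for E1 with E2, I1a with I1b and I3a with I3b.

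Those 3 comparisons called 193, 304 and 218 genes with a filter at 7 and 187, 309 and 246 with the mean of a gene's probe sets, both of which test fewer genes, and 217, 358 and 256 with values under 5 set to 5. Leaving out 1 array gave 313 to 361, 522 to 646 and 396 to 481.

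Genes above all other types numbered 11 in E1 without a filter. With a filter at 7 they numbered 3 in E1, 7 in E2, 2 in I1a, 1 in I1b, 75 in I2 and 3 in I3a. The mean of probe sets gave 3 in E1, quantile normalization 13 in I3a, and values under 5 set to 5 gave 3 in I1a and 4 in I3a. A gap of 2 left 0 in E1, 4 in E2, 2 in I1a, 1 in I1b, 36 in I2, 1 in I3a and 4 in I3b. Without the partner I3a had 36 and I3b 41, and without I1b and I3a E1 had 17, E2 25 and I3b 44. With 1 array per type, which loosens the rule by construction, counts were 15 to 19 in E1, 22 to 23 in E2, 12 to 14 in I1a, 7 to 13 in I1b, 196 to 204 in I2, 22 to 23 in I3a and 28 to 35 in I3b.

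The similarity of named pairs kept its side of 0.05 under each alternative run for it, and so did the 3 fast-spiking correlations. For the named pairs, mean r ran from 0.101 to 0.225, with exact permutation p of 0.0286, or 0.0381 by Spearman. None of these alternatives left out a pool. Signs turned for 8 named genes, counted among Gad1 and the named genes that differed by at least 1 log2 unit. Other differences under 1 log2 unit were not counted, and some of these also turned in I1 against I3. Slc6a5 did so without I3b, at 8.41 in I1a and 8.17 in I1b, against 8.47 in I3a and 7.53 in I3b. Calb2 did so without I3a, at 7.73 in I1a and 7.29 in I1b, against 3.44 in I3a and 9.86 in I3b. Of the 8, Mbp in E against I was 0.034 without I1b and I3a, and Kcnq3 between E1 and E2 was -0.21 with the mean of probe sets. When 1 pool or replicate was left out, Necab1 in E against I ran from -0.61 to 3.07. In I1 against I3, Gad1 ran from -1.13 to 0.37, Gabrb2 from -0.40 to 2.53, Vcan from -2.43 to 0.076, Bcan from -0.28 to 2.28 and Cnp from -3.37 to 0.64. No call rested on these signs except that of Kcnq3. Of all values of named genes under an alternative, most kept both direction and side of the threshold: 1083 of 1107 for E against I, 1057 of 1134 for I1 against I3, 600 of 635 for E1 with E2, 736 of 795 for I1a with I1b and 656 of 691 for I3a with I3b, while 71 in I1 against I3 were called under an alternative alone.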

Other observations

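All tests in this part were chosen after the results were seen, and the genes named here outside the fixed rule were chosen after their values were seen.

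Some of the genes that stood above every other pool in I2 are given here as examples, with no test of any group of genes. Gal, the peptide galanin, stood at 7.67 in I2 and at 4.15 or below in the other pools, and Cck, cholecystokinin, at 7.0 in I2 against 4.8 in I1a. The glycine receptor subunits Glra3 and Glra2 reached 6.50 and 5.93, and Kcnt2 reached 7.55. Dcc, a netrin receptor, at 7.02, Sema3c at 6.74 and Efnb2, an ephrin, at 8.62 are genes of axon guidance. Meis2, a homeobox transcription factor, stood at 12.60, and Synpr at 11.91. I2 was also the pool with the most genes 1 log2 unit or more below every other type, 50 against 2 in I1b to 23 in I3a.

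Slc6a2, the noradrenaline transporter, was at 8.18 in I2, while Th, the first enzyme of catecholamine synthesis, was at or within 0.02 of the floor in every pool. Dbh, which makes noradrenaline from dopamine, stood at 5.68 in I2 and at 5.6 to 6.09 elsewhere. Slc6a3 and Slc6a4, the dopamine and serotonin transporters, were at 2.43 and 2.46 in I2.

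Crh, Zic1, Pbx3 and Slc17a6 shared an order among types, with higher values in I1b than I1a and in I3a than I3b. Over all 4409 genes the I1a minus I1b and I3a minus I3b differences correlated at r = -0.203, which ranked 38th in size among all pairs of such differences between separate pools. Genes are not independent replicates, and the labels do not say whether a and b mean the same in both families.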
